A study of Homo sapiens with 12 samples.

How the data were processed

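Poly(A) RNA was sequenced from A549, an established human cell line from a non-small cell lung cancer. Per the labels, the cells stably carried either a control short hairpin RNA (shControl) or one against TRIM22 (shTRIM22), a RING-type E3 ubiquitin ligase of the tripartite motif family, and were sham-treated or taken 3 days after ionizing radiation. Per the labels' protocols, libraries were made from 1.3 µg of total RNA and fragments of 370 to 420 bp were selected. Each of the 4 groups holds 3 libraries, 12 in all.

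The authors deposited 1 table of raw read counts per gene, with no normalization, for 58735 genes. The submitters' processing notes name the human genome build hg38 and DESeq2 1.20.0 without a role. The aligner and the counting tool are not given in the sources used here, and neither is strandedness, so reads of overlapping genes on opposite strands cannot be told apart. The identifiers and coordinates of all 58735 genes equal those of GENCODE release 29, and coordinates are given on that build. Columns were matched to samples through the sample descriptions. The table holds 0 per-sample columns beyond those of the 12 libraries.

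The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group, with its minimum count of 10, which left 17094 genes. Libraries were scaled by TMM. A single model with 1 mean per group was fitted to all 12 libraries with robust dispersion estimates, and each comparison was a quasi-likelihood F-test with Benjamini-Hochberg adjustment over the 17094 genes. A gene was called at an adjusted p below 0.05, and a stricter count adds an absolute log2 fold change of at least 1. A list score is the mean log2 CPM of a list's genes in a library minus the mean of shControl sham. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Levels are TMM-scaled CPM, as mean ± SD over the 3 libraries of a group. Where all libraries of a group held 0 counts, the fold is a lower bound against 3 counts per library. Such bounds and the intervals on few counts cover counting error only.

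The 5 comparisons were irradiation in shControl cells, irradiation in shTRIM22 cells, knockdown without irradiation, knockdown after irradiation, and their interaction, which tests whether the log2 effect of irradiation differed between the cell populations. The lists of genes, 26 in all, were fixed before the data were examined, as were the tests and the rule for named genes. Of these lists, 24 had at least 5 genes tested and were tested against all other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 120 pairs of list and comparison. Members were counted by their adjusted p over all genes, and again with the adjustment over the list alone. All symbols of the lists were in the table. A list's median, mean and test differed in sign in 18 of the 120 pairs, of which 0 were called. Camera was repeated with an estimated correlation, where 18 of 55 called pairs stayed called, and fry was run as a test of whether a list moves on balance in 1 direction.

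Named genes are TRIM22 in every comparison, the 5 called protein-coding genes with the largest rise and the 5 with the largest fall among those with a mean of at least 2 CPM and compared groups that did not overlap (no such condition for the interaction), and up to 4 called members with the smallest p of each list called by camera. Chance alone gives no overlap for 10% of genes with 3 libraries against 3. Genes named outside this rule are marked as chosen after their values were seen. XIST and genes of the Y chromosome were left out of the text. Some genes that met the rule for named genes are not reported here.

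The total count per library ran from 14468386 to 17872154. In simulated counts for 17094 genes with the means, library sizes and dispersions of these libraries and 200 changed genes, the same steps recovered 60% of 1.5-fold, 68% of 2-fold, 90% of 3-fold and 94% of 4-fold changes for knockdown without irradiation, with 9 false calls among 165. For the interaction they recovered 34%, 62%, 72% and 76% of the same fold sizes, with 10 false calls among 132. All libraries were drawn with the same dispersion per gene, whereas in the data shTRIM22 sham replicate 3 stood apart from its group. For knockdown without irradiation 8116 genes were called in the data, against 200 changed genes simulated. These rates therefore need not hold for the real libraries. In a simulation of knockdown after irradiation over 17094 genes, camera called 0 of 20 unchanged lists of 25 genes and the 1 list shifted by 1.3-fold. Genes were drawn independently of each other there, so false calls of lists whose genes move together were not tested.

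Replicate numbers were checked by the correlation of library deviations from the group means across genes. Between shControl sham and shTRIM22 sham all 3 same-number pairs exceeded 0.1 (0.160 to 0.282, against -0.266 to 0.125 for other pairs). Pairs of replicate 1 with replicate 2 also exceeded 0.1, at 0.116 and 0.125. Replicate 3 of both groups deviated with the GC content of transcripts in the same direction (Spearman rho = 0.132 and 0.372). Pairing and such a shared trend cannot be told apart here. The numbers were therefore treated there as possible pairs, from the data and not from the labels.

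Alternatives fixed before the data were examined were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of 1 CPM in 6 libraries, a fit of the 2 compared groups alone, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were limma-voom with sample weights, an offset per library for the GC content of transcripts, the block in a fit of the sham groups alone and with that offset, and leaving out shTRIM22 sham replicate 3 from comparisons that do not contain its group.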

Results

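The series asked how knockdown of TRIM22 changes the transcriptome of A549 cells and its response to ionizing radiation. Counts came from 4 groups of 3 libraries: shControl sham, shControl irradiated, shTRIM22 sham and shTRIM22 irradiated, the irradiated cells taken 3 days after exposure. Total counts ran from 14468386 in shControl irradiated replicate 1 to 17872154 in shTRIM22 sham replicate 1. The labels call the 3 libraries of a group biological replicates without saying whether they were separate cultures or days, so p-values measure the spread between these libraries. The labels name 1 stable population per hairpin, so an effect of losing TRIM22 and any other difference between the populations are not separated by the design, and "knockdown" here stands for shTRIM22 against shControl cells. The labels give neither the radiation dose nor when sham cells were taken. A difference in time of harvest, if any, is thus not separated from irradiation.

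TRIM22 (ENSG00000132274, chromosome 11, 5689689 to 5737089 on the plus strand of GRCh38) carried the labels. Its level was 2.28 ± 0.538 CPM in shControl sham and 0.308 ± 0.0169 CPM in shTRIM22 sham libraries (mean ± SD, n = 3), which left 13.8% of the shControl level (log2 fold change -2.85 ± 0.32 SE, edgeR adjusted p = 1.92e-06). After irradiation it was 17.6 ± 0.969 CPM in shControl and 2.00 ± 0.579 CPM in shTRIM22 libraries, 11.4% of the shControl level (-3.14 ± 0.19, adjusted p = 3.8e-09). Irradiation raised TRIM22 7.72-fold in shControl and 6.35-fold in shTRIM22 cells, and these log2 effects did not differ past the threshold (interaction -0.28 ± 0.47, adjusted p = 0.805). TRIM22 overlaps TRIM5 in the annotation. The count of TRIM22 in single shTRIM22 sham libraries was 5 or 6.

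**Figure D1:**
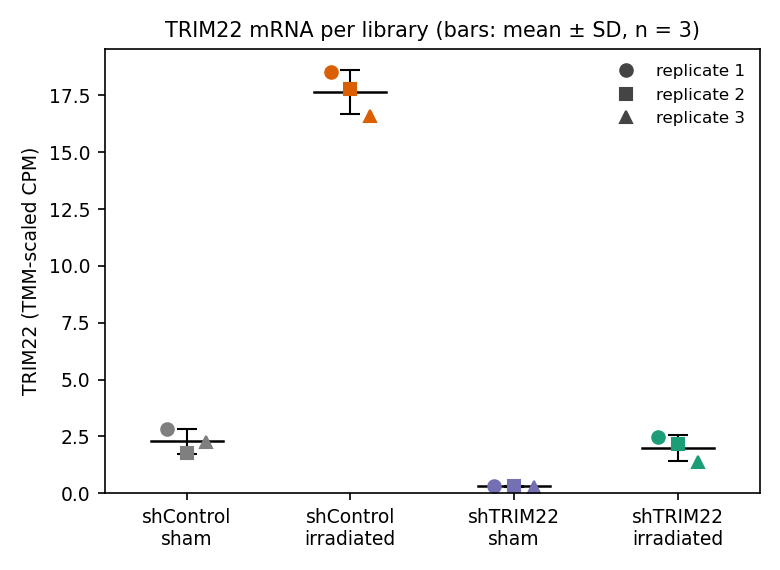
TRIM22 in TMM-scaled CPM (vertical axis) for each of the 12 libraries by group (horizontal axis), with the group mean and SD as bars (n = 3). Irradiated shControl libraries lie between 16.6 and 18.5 CPM, and all shTRIM22 libraries lie at or below 2.47 CPM.

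One library stood apart. In shTRIM22 sham replicate 3 mitochondrially encoded genes took 2.67% of all counts, against 9.12% and 11.4% in the other libraries of its group and 10.8% to 14.4% in all other libraries. The chi-square over genes of its counts against the other libraries of its group was 66.2 and 96.1 per degree of freedom, where the other pairs of replicates within a group gave 2.58 to 8.10. Mitochondrially encoded genes are included in it, so it partly restates their low share. Nuclear genes alone differed by 2.49 times the SD between the other libraries of the group. All pairs of replicates differed by more than sampling noise, so none was counted as 1 library. This library widened the shared estimate of the spread: the common biological coefficient of variation was 9.70% with it and 5.46% without it.

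**Figure D2:**
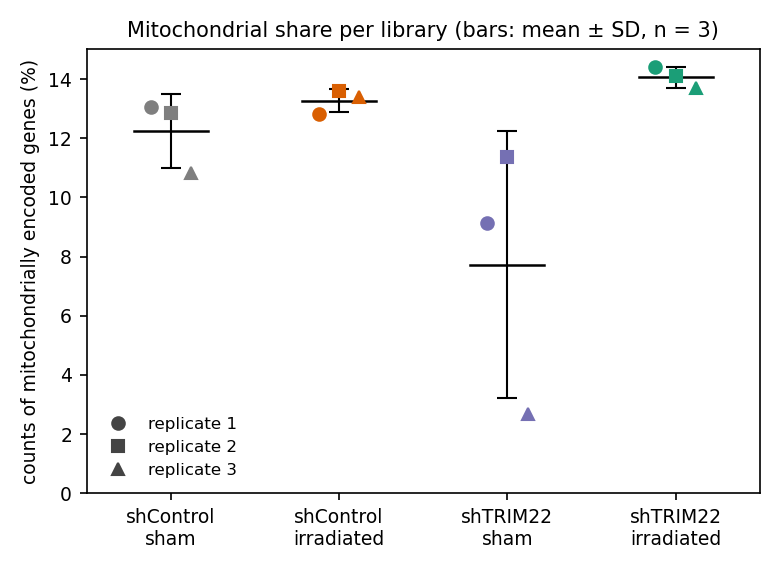
Share of counts in mitochondrially encoded genes in percent (vertical axis) per library and group (horizontal axis), with the group mean and SD as bars (n = 3). The shTRIM22 sham replicate 3 lies at 2.67% and all other libraries between 9.12% and 14.4%.

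Irradiated shControl cells carried more mRNA of p53 targets and less of nuclear lamina and chromatin genes. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the p21 inhibitor of cyclin-dependent kinases, rose from 162 ± 2.18 to 599 ± 19.8 CPM (mean ± SD, n = 3), 3.69-fold. MDM2, the ubiquitin ligase that restrains p53, rose 3.62-fold. Of 30 p53 target genes tested, 29 rose and 0 fell (29 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.10 (camera adjusted p = 2.78e-105). Of 30 mitotic and G2/M genes, 27 fell and 0 rose (0 higher and 29 lower adjusted over the list alone), with a median of -0.83 (camera adjusted p = 1.35e-24, adjusted p = 0.0826 with an estimated correlation).

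Among the p53 targets, ZMAT3, a zinc-finger RNA-binding protein, rose from 24.3 ± 1.70 to 74.5 ± 2.33 CPM, and TP53INP1, a p53-induced nuclear protein, rose from 15.2 ± 1.27 to 55.9 ± 0.192 CPM. The list holds TRIM22 itself. The mitotic motor genes KIF11, KIF20A and CENPE fell 2.37-fold, 2.43-fold and 2.57-fold, and CDK1, the mitotic kinase, fell 1.69-fold. DNA replication genes fell as well, 20 of 30 with 1 higher (2 higher and 24 lower adjusted over the list alone, camera adjusted p = 8.88e-13, adjusted p = 0.127 with an estimated correlation). ORC6, GINS2 and MCM6, parts of the origin recognition complex and the replicative helicase, changed by -1.04 ± 0.12, -1.53 ± 0.19 and -0.73 ± 0.10 (log2 fold change ± SE), and UHRF1, needed to maintain DNA methylation at replication, by -0.78 ± 0.10. Of 28 DNA repair genes, 12 fell and 0 rose (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 1.33e-07, adjusted p = 0.0817 with an estimated correlation). Among them were BRCA1 (-1.31), its partner BARD1 (2.55-fold lower), the helicase gene BLM (-1.34) and RAD51AP1 (-1.17). Of 13 nuclear lamina and chromatin genes that are lost in senescent cells, 11 fell (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 2.84e-12, adjusted p = 0.00771 with an estimated correlation). They include LMNB1, the gene of lamin B1, at 2.48-fold lower, HMGB2 at 2.06-fold lower, SMC4 (-0.73) and LBR (-0.48).

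Secreted factors of senescent cells and NF-kB targets rose as lists. Of 25 secreted factors of senescent cells tested, 13 rose and 2 fell (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.66e-08, adjusted p = 0.00261 with an estimated correlation). The metalloproteinase inhibitor gene TIMP2 rose 1.67-fold. Of 25 NF-kB target genes, 13 rose and 0 fell (14 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.56e-08, adjusted p = 0.00261 with an estimated correlation). The neutrophil chemokine genes CXCL1 and CXCL8, which are on both lists, rose 2.23-fold and 1.88-fold, SOD2, the mitochondrial superoxide dismutase, 1.80-fold and TNFAIP2 1.65-fold. Of 33 interferon-stimulated genes, 14 rose and 0 fell (15 higher and 0 lower adjusted over the list alone, camera adjusted p = 8.92e-06, adjusted p = 0.00771 with an estimated correlation). Among them were STAT2 (0.57), PARP9 (0.68) and IFIT3 (1.01). Of 17 genes of MHC class I antigen presentation, 7 rose and 0 fell (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00033, adjusted p = 0.132 with an estimated correlation), with B2M, its light chain, 1.48-fold higher, the immunoproteasome subunit gene PSMB8 1.74-fold, CALR 1.46-fold and TAPBP 1.27-fold. PSMB8 overlaps PSMB9.

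Lists that moved less were also called. Of 24 sterol synthesis and uptake genes, 12 rose and 2 fell (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000896, adjusted p = 0.11 with an estimated correlation). HMGCS1 (0.45) and MSMO1 (0.55) rose. Of 23 genes of the unfolded protein response and ATF4, 3 rose and 8 fell (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.158 with an estimated correlation). Those that fell most clearly were PHGDH and PSAT1, enzymes of serine synthesis (-1.41 and -0.67), TRIB3 (-0.99) and CHAC1, a glutathione-degrading enzyme (-0.80). Of 26 BCL2 family and caspase genes, 9 rose and 4 fell (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.0817 with an estimated correlation). The pro-apoptotic BAX (0.99), BBC3 (0.70) and BID (0.54) were higher and HRK (-1.75) was lower. Of 27 autophagy and lysosome genes, 6 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.0817 with an estimated correlation). Among them were the cathepsin genes CTSD (0.51) and CTSB (0.63), ATG2A (0.80) and WIPI2 (0.30). Of 19 epithelial genes, 6 rose and 0 fell (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.0942 with an estimated correlation). KRT8 (0.58), ELF3 (0.49), CLDN2 (0.53) and CDH1 (0.42) were higher, where KRT8 can share reads with its many processed copies. The call of the epithelial list was lost in 3 of 13 alternatives. Of 20 immediate early and heat shock genes, 2 rose and 9 fell (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.207 with an estimated correlation). KLF2 (-0.89), MYC (-0.43) and IER2 (-0.38) fell and HSPA8 (0.32) rose, and the list call was lost in 2 of 13 alternatives. The lists not called held 4 higher and 1 lower of 23 mesenchymal genes, 1 higher and 0 lower of 9 lung alveolar and airway genes, 7 higher and 1 lower of 25 NRF2 targets, 4 higher and 2 lower of 24 hypoxia and glycolysis genes, 2 higher and 0 lower of 6 TRIM genes next to TRIM22, 0 higher and 1 lower of 28 ribosomal protein genes and 0 higher and 0 lower of 13 mitochondrially encoded genes. Markers of other cells were 1 higher and 0 lower of 5 fibroblast markers, 0 higher and 0 lower of 4 endothelial markers, 1 higher and 0 lower of 3 blood cell markers and 1 higher and 0 lower of 7 genes of kidney or cervix lines.

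The protein-coding genes with the largest rises were CYGB (cytoglobin, 8.89-fold), FLG (filaggrin, 5.43-fold), PTAFR (the receptor of platelet-activating factor, 5.27-fold), SAA2 (a serum amyloid A, 4.86-fold) and SPATA18 (4.57-fold). CYGB overlaps PRCD, FLG overlaps an antisense gene, and SAA2 can share reads with its near-identical neighbour SAA1. The largest falls were in DHRS2, a short-chain dehydrogenase (9.79 ± 1.45 to 1.74 ± 0.644 CPM, 5.63-fold), HRK (3.37-fold), U2AF1 (3.28-fold), the kinetochore gene SKA1 (3.27-fold) and the helicase gene PIF1 (3.19-fold). U2AF1 has a near-identical copy in this genome build, its adjusted p was 0.0382, and the call was lost in 10 of 16 alternatives. In all, 3107 of 17094 genes passed the edgeR test, 1820 higher and 1287 lower, and 432 of them changed at least 2-fold. The count was 5260 without shTRIM22 sham replicate 3, which is not among the compared libraries but shares the estimate of the spread, and 5224 when only the 2 compared groups were fitted.

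In shTRIM22 cells irradiation lowered the genes of DNA replication and raised p53 targets, interferon-stimulated genes and NF-kB targets. CDC20, an activator of the anaphase-promoting complex, fell 3.41-fold (log2 fold change -1.77 ± 0.17 SE, n = 3). Of 30 DNA replication genes, 28 fell and 0 rose, with a median log2 fold change of -0.90 (0 higher and 28 lower adjusted over the list alone, camera adjusted p = 1.41e-29, adjusted p = 0.038 with an estimated correlation). CDKN1A rose from 362 ± 5.57 to 644 ± 8.18 CPM (mean ± SD), 1.78-fold, and MDM2 rose 1.56-fold. Of 30 p53 targets, 19 rose and 1 fell, with a median of 0.41 (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.39e-10, adjusted p = 0.00261 with an estimated correlation).

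Of 30 mitotic and G2/M genes, 28 fell and 0 rose (0 higher and 29 lower adjusted over the list alone, camera adjusted p = 2.31e-33, adjusted p = 0.0546 with an estimated correlation). Among them were the mitotic kinase genes CDK1 (2.29-fold lower) and AURKB (2.81-fold) and the motor gene KIF11 (2.30-fold). UHRF1 fell 2.19-fold, and the helicase subunit genes MCM7, MCM4 and MCM5 fell 2.32-fold, 1.79-fold and 1.88-fold. MCM7 overlaps AP4M1. Of 28 DNA repair genes, 0 rose and 18 fell (0 higher and 18 lower adjusted over the list alone, camera adjusted p = 2.13e-12, adjusted p = 0.0364 with an estimated correlation). Among them were FANCD2 of the Fanconi pathway (-1.47 ± 0.14, log2 fold change ± SE), BLM (-1.65 ± 0.18), BRCA1 (-1.25 ± 0.14) and the helicase gene BRIP1 (-1.10 ± 0.13). Of 13 nuclear lamina and chromatin genes, 0 rose and 11 fell (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 4.53e-13, adjusted p = 0.00725 with an estimated correlation). HMGB2 (-1.22), SMC4 (-0.97), LBR (-0.67) and the DNA methyltransferase gene DNMT1 (-0.60) were lower. Of 23 genes of the unfolded protein response and ATF4, 0 rose and 14 fell (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 4.58e-09, adjusted p = 0.0348 with an estimated correlation). PHGDH (-1.58), CHAC1 (-1.14), PSAT1 (-0.88) and the lipoprotein receptor gene VLDLR (-0.79) fell.

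Interferon-stimulated genes were higher after irradiation. Of 33 of these genes tested, 18 rose and 0 fell (23 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.39e-10, adjusted p = 0.00208 with an estimated correlation). IFIT1 rose from 8.16 ± 0.835 to 17.0 ± 1.36 CPM. PARP9 and STAT2 (1.83-fold and 1.47-fold) were higher. Of 25 NF-kB targets, 13 rose and 0 fell (14 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.66e-08, adjusted p = 0.00261 with an estimated correlation), with the chemokine genes CXCL8 (1.10), CXCL3 (1.08) and CXCL1 (0.92) and with SOD2 (0.53). Of 25 secreted factors of senescent cells, 14 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.64e-08, adjusted p = 0.00261 with an estimated correlation). Among them was the tissue plasminogen activator gene PLAT (3.15-fold). Of 25 targets of NRF2, the regulator of antioxidant genes, 11 rose and 2 fell (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000896, adjusted p = 0.16 with an estimated correlation). The aldo-keto reductase genes AKR1C1 (0.90), AKR1C2 (0.48) and AKR1C3 (0.44) and the transporter gene ABCC3 (0.49) were higher. The AKR1C genes are near-identical paralogs and can share reads. Of 27 autophagy and lysosome genes, 10 rose and 3 fell (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.11 with an estimated correlation). Among them were ATG2A (0.65), CTSB (0.57), CTSD (0.38) and NBR1 (0.26), and the list call was lost in 2 of 12 alternatives. Of 20 immediate early and heat shock genes, 3 rose and 10 fell (3 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.127 with an estimated correlation). KLF2 (-1.67), JUN (-0.43) and DUSP1 (-0.38) fell and FOSB (0.68) rose.

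Ribosomal protein genes and mitochondrially encoded genes were called in opposite directions. Of 28 ribosomal protein genes, 0 rose and 13 fell (0 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00097, adjusted p = 0.189 with an estimated correlation), with RPS15 (-0.48), RPS2 (-0.55) and RPL8 (-0.35) lower, genes whose many processed copies can share their reads. Of 13 mitochondrially encoded genes, 0 rose and 0 fell singly (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00637, adjusted p = 0.545 with an estimated correlation), with a median log2 fold change of 1.15 that was 0.64 without shTRIM22 sham replicate 3, whose mitochondrial share was 2.67%. Without that library 10 of the 13 rose and the list stayed called (camera adjusted p = 8.91e-05). Markers of other cells were 1 higher and 0 lower of 5 fibroblast markers, 2 higher and 0 lower of 4 endothelial markers, 2 higher and 0 lower of 3 blood cell markers and 0 higher and 1 lower of 7 genes of kidney or cervix lines.

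The largest rises were in PTAFR (7.09-fold), the aminopeptidase gene ANPEP (4.27-fold), PHEX (3.89-fold), ITIH5 (3.71-fold) and ALDH3A1, an aldehyde dehydrogenase (94.8 ± 7.30 to 343 ± 32.7 CPM, 3.62-fold). The largest falls were in DHRS2 (32.8 ± 2.14 to 3.24 ± 0.911 CPM, 10.1-fold), the telomerase gene TERT (4.11-fold), the kinesin genes KIF18B (4.04-fold) and KIF15 (3.95-fold) and DIAPH3 (3.95-fold). In all, 4702 genes passed the edgeR test, 2306 higher and 2396 lower, and 698 changed at least 2-fold. The count was 5389 without shTRIM22 sham replicate 3 and 2912 when only the 2 compared groups were fitted. Of the genes called, 1920 were also called in shControl cells, 1076 higher in both, 806 lower in both and 38 in opposite directions, where independent lists would share 246 higher and 180 lower. The log2 fold changes of the 17094 genes correlated across genes at Pearson r = 0.507, and at 0.642 over genes with a mean above 2 CPM, genes not being independent replicates. These irradiation comparisons share no library.

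Without irradiation, shTRIM22 cells carried more mRNA of p53 targets and of sterol synthesis genes than shControl cells, and less of the mucin genes MUC5B and MUC5AC and of FOS. CDKN1A rose from 162 ± 2.18 to 362 ± 5.57 CPM (mean ± SD, n = 3), 2.23-fold. MUC5B, a gel-forming airway mucin, fell from 7802 ± 531 to 1807 ± 410.1 CPM, 4.32-fold, and MUC5AC, another, from 246 ± 19.6 to 28.0 ± 6.76 CPM, 8.79-fold. The immediate early gene FOS fell from 839 ± 26.5 to 157 ± 3.95 CPM, 5.35-fold.

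Of 30 p53 targets, 24 rose and 2 fell (26 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.93e-14, adjusted p = 0.00208 with an estimated correlation), with a median log2 fold change of 0.84. The nuclease gene AEN (1.30 ± 0.0661, log2 fold change ± SE), ZMAT3 (1.55 ± 0.0849) and the sestrin gene SESN1 (1.74 ± 0.10) rose, while TRIM22, itself on the list, fell. Of 30 DNA replication genes, 23 rose and 1 fell (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.61e-06, adjusted p = 0.29 with an estimated correlation). The thymidine kinase gene TK1 (1.40), GINS2 (1.16), UHRF1 (1.04) and MCM4 (0.80) were higher. Of 28 DNA repair genes, 12 rose and 2 fell (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0165, adjusted p = 0.344 with an estimated correlation). Among them were PRKDC, the catalytic subunit of DNA-dependent protein kinase (0.56), and the Fanconi genes FANCI (0.85), FANCD2 (1.02) and FANCM (0.94). Of 30 mitotic and G2/M genes, 6 rose and 2 fell, and the list was not called. Of 24 sterol synthesis and uptake genes, 19 rose and 2 fell (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.24e-06, adjusted p = 0.0403 with an estimated correlation). SQLE rose 1.69-fold and MSMO1 2.29-fold. Of 26 BCL2 family and caspase genes, 11 rose and 5 fell (12 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0444, adjusted p = 0.111 with an estimated correlation). PMAIP1 (1.38) and BBC3 (0.96), pro-apoptotic members, and the caspase gene CASP2 (0.96) were higher. The call of this list was lost in 5 of 14 alternatives, among them leaving out shTRIM22 sham replicate 3 (adjusted p = 0.0507) and the replicate block with an offset for GC content (adjusted p = 0.0809).

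Of 25 NRF2 targets, 7 rose and 15 fell (9 higher and 15 lower adjusted over the list alone, camera adjusted p = 2.39e-07, adjusted p = 0.0632 with an estimated correlation). AKR1C2 fell from 2530 ± 48.3 to 863 ± 29.8 CPM, ABCC3 fell 3.05-fold, AKR1B10 2.87-fold and SLC7A11, the cystine transporter, 2.57-fold. Of 9 lung alveolar and airway genes, 0 rose and 4 fell (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000735, adjusted p = 0.0525 with an estimated correlation), namely both mucins, FOXA2, a forkhead factor of endoderm (16.9 ± 1.39 to 4.17 ± 0.492 CPM), and AGER (-1.33). Of 25 NF-kB targets, 2 rose and 12 fell (2 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.0632 with an estimated correlation). SOD2 (-0.92), TNFAIP3, an inhibitor of NF-kB signaling (-1.03), CXCL8 (-0.92) and CXCL2 (-0.48) fell. Of 20 immediate early and heat shock genes, 7 rose and 9 fell (7 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00177, adjusted p = 0.127 with an estimated correlation), FOSB (-2.68) and JUNB (-1.09) lower and KLF2 (0.87) higher. Of 5 fibroblast markers tested, 2 rose and 0 fell, of 3 blood cell markers 0 rose and 2 fell, of 4 endothelial markers 1 rose and 2 fell, and of 7 genes of kidney or cervix lines 2 rose and 2 fell.

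Among single genes, CA9, the hypoxia-induced carbonic anhydrase IX, was at 8.41 ± 0.591 CPM in shControl sham libraries and had 0 counts in all 3 shTRIM22 sham libraries, at least 48.4-fold lower. APOH, a plasma apolipoprotein, held 309 counts in shControl and 3 in shTRIM22 libraries, a ratio of 108 (95% interval for counting error 36.5 to 525). CACNA1G, a calcium channel gene, fell 14.5-fold and the transcription factor genes EGR1 and EGR2 fell 10.3-fold and 9.38-fold. The largest rises were in ALPP (placental alkaline phosphatase), CYP1A1 (a xenobiotic-induced cytochrome P450), CD79A, the collagen gene COL3A1 and PAG1 (0.922 ± 0.203 to 16.9 ± 2.09 CPM, 18.1-fold). The first 4 held only 5, 6, 9 and 11 counts over the 3 shControl sham libraries. Their count ratios, with 95% intervals for counting error, were 66.7 (28.3 to 207) for ALPP, 37.0 (16.7 to 102) for CYP1A1, 25.3 (13.1 to 56.0) for CD79A and 18.9 (10.3 to 38.3) for COL3A1. ALPP has near-identical paralogs and can share reads with them. CA9 overlaps ARHGEF39. In all, 8116 genes passed the edgeR test, 4342 higher and 3774 lower, and 1997 changed at least 2-fold. Without shTRIM22 sham replicate 3 the count was 8692, and 7376 of the 8116 genes remained.

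After irradiation, shTRIM22 cells had less mRNA of immediate early genes than shControl cells, while p53 targets were not called as a list. Of 20 lung alveolar and airway genes listed only 9 were tested. Of these, 4 were lower, mucins MUC5AC and MUC5B among them, and 1 was higher. MUC5AC fell from 489 ± 108 to 46.3 ± 5.18 CPM (mean ± SD, n = 3), 10.6-fold, and MUC5B from 9586 ± 1087 to 2300 ± 182 CPM, 4.17-fold. Of 30 p53 targets, 8 rose and 6 fell (9 higher and 9 lower adjusted over the list alone), with a median log2 fold change of 0.08 and a camera adjusted p = 0.594. Of 30 DNA replication genes, 9 rose and 2 fell, and of 30 mitotic genes 0 rose and 5 fell, with neither list called.

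Of 20 immediate early and heat shock genes, 2 rose and 10 fell (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.41e-06, adjusted p = 0.0364 with an estimated correlation). FOS fell 3.65-fold, FOSB 3.48-fold, JUN 2.23-fold and JUNB 2.13-fold. Of 25 NRF2 targets, 6 rose and 15 fell (7 higher and 15 lower adjusted over the list alone, camera adjusted p = 1.04e-05, adjusted p = 0.0889 with an estimated correlation). AKR1B10 (-1.49 ± 0.0702, log2 fold change ± SE), AKR1C2 (-1.34 ± 0.0597), ABCC3 (-1.28 ± 0.0559) and SLC7A11 (-1.10 ± 0.0685) were lower. Of 9 lung alveolar and airway genes, 1 rose and 4 fell (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000141, adjusted p = 0.0364 with an estimated correlation), FOXA2 (-1.98) falling and LAMP3, a gene of alveolar type II cells (1.52), rising. Of 25 NF-kB targets, 3 rose and 8 fell (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00807, adjusted p = 0.0584 with an estimated correlation). SOD2 (-1.24), TNFAIP2 (-0.99), TNFAIP3 (-0.90) and CXCL8 (-0.73) fell. Of 24 sterol synthesis and uptake genes, 13 rose and 1 fell (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.0817 with an estimated correlation). MSMO1 (0.90) and SQLE (0.77) were higher. Of 27 autophagy and lysosome genes, 10 rose and 4 fell (14 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0468, adjusted p = 0.127 with an estimated correlation). GABARAPL1 (0.76), CTSL (0.55), MCOLN1 (0.55) and WIPI2 (0.35) were higher. This call was lost in 6 of 13 alternatives. Of 5 fibroblast markers tested, 3 rose and 0 fell, of 3 blood cell markers 0 rose and 2 fell, of 4 endothelial markers 1 rose and 1 fell, and of 7 genes of kidney or cervix lines 2 rose and 2 fell.

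CA9 held 212 counts in irradiated shControl and 2 in irradiated shTRIM22 libraries, a ratio of 109 (95% interval for counting error 29.7 to 902). APOH fell 15.1-fold, CACNA1G 9.19-fold and FST, the activin-binding follistatin, 8.07-fold. The largest rises were in REEP1 (1.60 ± 0.212 to 18.5 ± 1.95 CPM, 11.5-fold), the betaine and GABA transporter gene SLC6A12 (10.3-fold), the endothelial cadherin gene CDH5 (9.13-fold), CD79A (9.08-fold) and PAG1 (8.78-fold). In all, 6092 genes passed the edgeR test, 3015 higher and 3077 lower, and 1213 changed at least 2-fold, against 7943 without shTRIM22 sham replicate 3. Of the genes called, 4840 were also called without irradiation, 2410 higher in both, 2408 lower in both and 22 in opposite directions, where independent lists would share 766 and 679. The knockdown effects without and after irradiation correlated across genes at Pearson r = 0.768, and at 0.841 over genes with a mean above 2 CPM. These knockdown comparisons share no library.

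The interaction tested whether irradiation had another effect in shTRIM22 than in shControl cells. A lower log2 effect in shTRIM22 cells can be a smaller rise or a larger fall. The p53 targets rose less in shTRIM22 cells: of 30 tested, 21 had a lower and 0 a higher log2 effect (0 higher and 26 lower adjusted over the list alone, camera adjusted p = 5.57e-60, adjusted p = 1.31e-05 with an estimated correlation), with a median difference of -0.76. CDKN1A rose 3.69-fold in shControl and 1.78-fold in shTRIM22 cells (interaction -1.05 ± 0.0719 SE, edgeR adjusted p = 1.22e-06), from 162 ± 2.18 and 362 ± 5.57 CPM to 599 ± 19.8 and 644 ± 8.18 CPM (mean ± SD, n = 3). MDM2 rose 3.62-fold and 1.56-fold (interaction -1.22 ± 0.0867), and AEN (-1.08) and ZMAT3 (-1.18) also differed. The p53 list score stood at 1.23 ± 0.0207 in shControl irradiated, 0.682 ± 0.0220 in shTRIM22 sham and 1.11 ± 0.0310 in shTRIM22 irradiated libraries, relative to shControl sham. The score includes TRIM22, the target of the hairpin, at 13.8% and 11.4% of the shControl level without and after irradiation. Its loss lowers both shTRIM22 scores, so the gap between 1.11 and 1.23 partly reflects the knockdown itself. The p53 list was the 1 of 11 called lists that was also called with an estimated correlation.

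**Figure D3:**
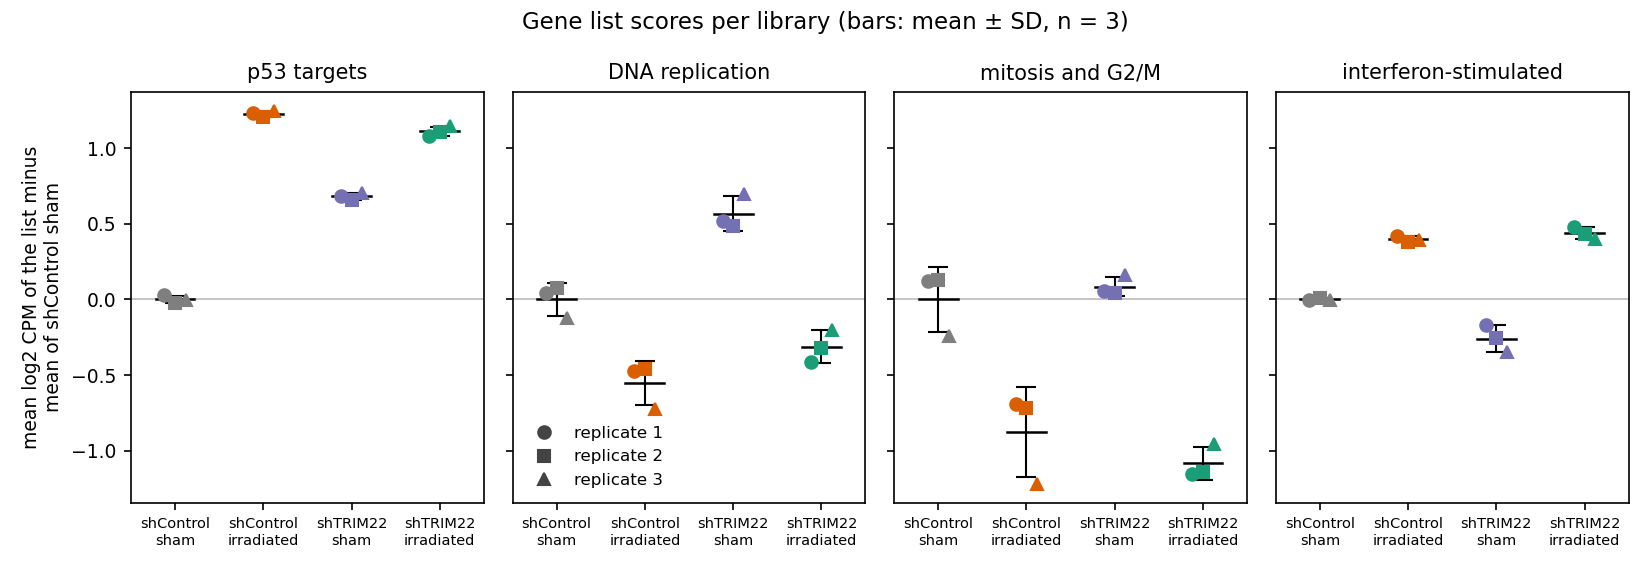
Mean log2 CPM of the genes of a list minus the mean of shControl sham (vertical axis) in each library by group (horizontal axis), for p53 targets, DNA replication, mitosis and G2/M, and interferon-stimulated genes, with the group mean and SD as bars (n = 3). The p53 score is 0.682 in shTRIM22 sham and 1.11 in shTRIM22 irradiated libraries, and the replication score is 0.57 and -0.31 there. The p53 list includes TRIM22, the target of the hairpin, which lowers both of these p53 scores.

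The other called lists held few genes that differed singly. By their medians, DNA replication genes fell further with irradiation in shTRIM22 cells (-0.90) than in shControl cells (-0.59). Of 30 tested, 4 had a lower and 0 a higher log2 effect (0 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.33e-07, adjusted p = 0.234 with an estimated correlation). These were MCM4 (-0.62), PCNA, the sliding clamp (-0.57), CDT1 (-0.97) and TYMS (-0.72). The last 2 lost their calls in 10 and 11 of 20 alternatives. TYMS overlaps its antisense gene TYMSOS. Of DNA repair genes, 28 tested had 0 higher and 1 lower (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.371 with an estimated correlation), FANCD2 (-1.18), and this list call was lost in 6 of 18 alternatives. Of genes of MHC class I presentation, 17 tested had 0 higher and 1 lower (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.183 with an estimated correlation), B2M (-0.39). Without shTRIM22 sham replicate 3 the median of this list moved from -0.37 to -0.21. Of genes of the unfolded protein response and ATF4, 23 tested had 0 higher and 1 lower (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000791, adjusted p = 0.138 with an estimated correlation), VLDLR (-0.67). Of sterol genes, 24 tested had 0 higher and 1 lower (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.142 with an estimated correlation). Their median moved from -0.24 to -0.15 without shTRIM22 sham replicate 3. Of NRF2 targets, 25 tested had 2 higher and 0 lower (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00447, adjusted p = 0.207 with an estimated correlation), the transporter genes ABCC2 (0.44) and ABCC3 (0.33), the latter lost in 11 of 20 alternatives. Of ribosomal protein genes, 28 tested had 0 higher and 1 lower (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0308, adjusted p = 0.378 with an estimated correlation), RPS19 (-0.90), lost in 12 of 20 alternatives, and the list call in 7 of 18.

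Among mitotic and G2/M genes, 30 tested had 0 higher and 0 lower (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000806, adjusted p = 0.517 with an estimated correlation), with a median of -0.37, and the call was lost in 3 of 18 alternatives. Among interferon-stimulated genes, 33 tested had 0 higher and 0 lower (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00715, adjusted p = 0.0546 with an estimated correlation), with a median of 0.25. Among mitochondrially encoded genes, 13 tested had 0 higher and 0 lower (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000896, adjusted p = 0.489 with an estimated correlation), with a median of 0.94 that was 0.45 without shTRIM22 sham replicate 3, where the list stayed called (camera adjusted p = 9.21e-05) with 1 gene higher. The call was lost in 2 of 18 alternatives. Of the markers of other cells, 1 of 5 fibroblast markers and 1 of 7 genes of kidney or cervix lines had a lower effect, and 0 of 4 endothelial and 0 of 3 blood cell markers differed.

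**Figure D4:**
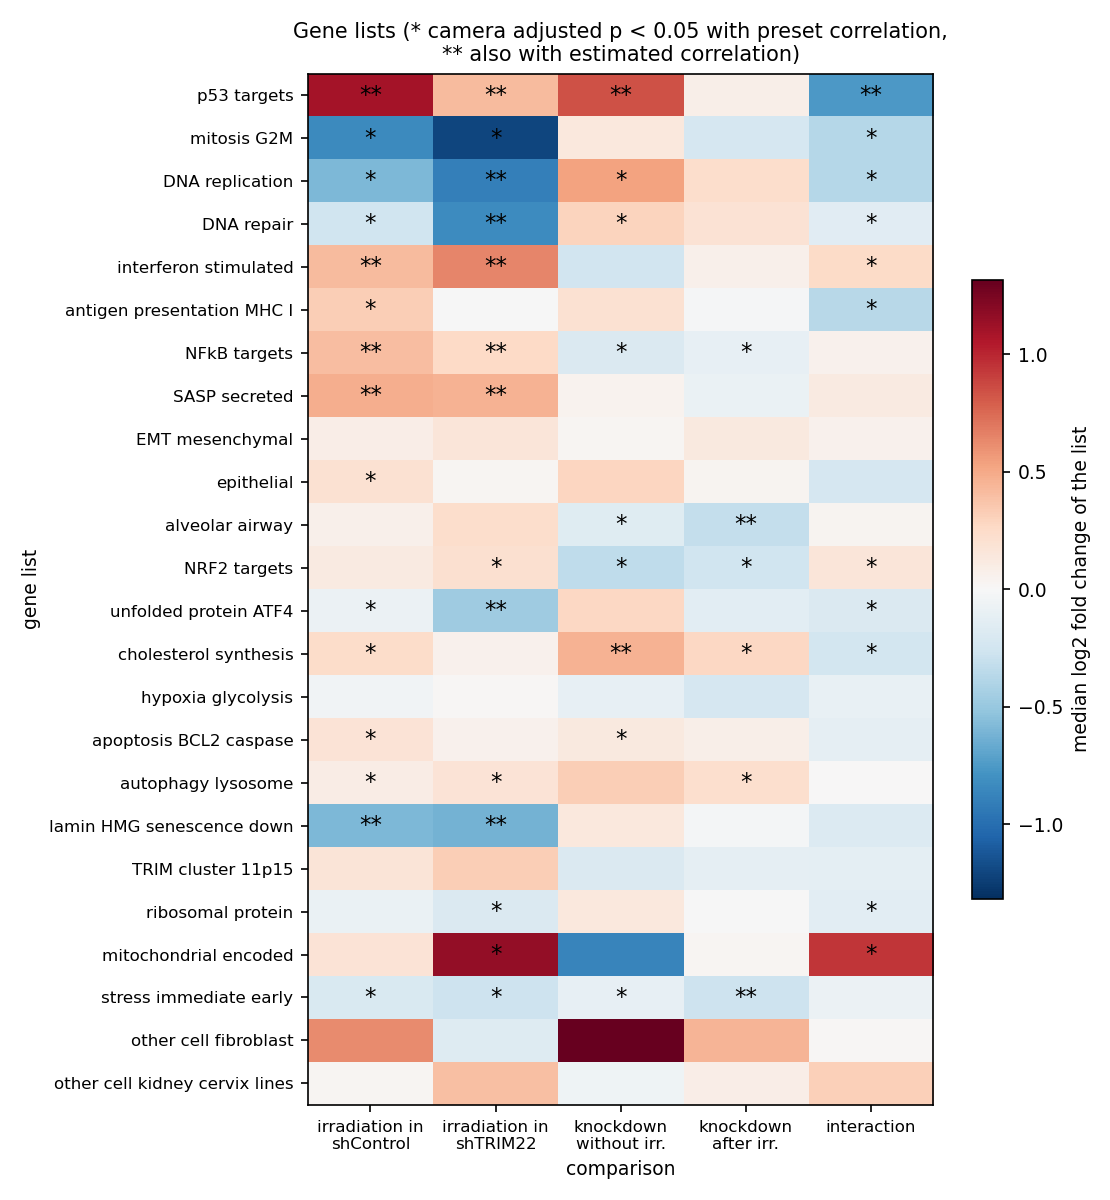
Median log2 fold change (colour scale) of each tested gene list (vertical axis) in each of the 5 comparisons (horizontal axis), with 1 star for lists called by camera with the preset correlation and 2 stars for those also called with an estimated correlation. The p53 list has a median of 1.10 for irradiation in shControl cells and -0.76 for the interaction, and both carry 2 stars.

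The protein-coding genes whose irradiation effect was most above that in shControl cells were APOH (2.66 ± 0.60, log2 difference ± SE), PLEKHG6 (1.68 ± 0.25), MAP1A (1.23 ± 0.27), ADGRE1 (1.14 ± 0.24) and the microtubule-associated protein gene MAP2 (1.04 ± 0.20). APOH lost its call in 13, MAP1A in 8 and ADGRE1 in 6 of 20 alternatives. Most below it were ALPP (-3.13 ± 0.55), the acute-phase genes SAA2 (-2.65 ± 0.29) and SAA1 (-2.20 ± 0.25), which can share reads, the peroxidasin gene PXDN (-1.66 ± 0.35) and FLG (-1.66 ± 0.35). PXDN lost its call in 6 and FLG in 7 of 20 alternatives. In all, 276 of 17094 genes passed the edgeR test for the interaction, 89 higher and 187 lower, and 40 differed at least 2-fold. The count was 578 with the Wald test of DESeq2 and 754 without the filter on low counts. It was 1185 without shTRIM22 sham replicate 3, 915 without replicate 2 of that group, and 111 to 138 when any 1 of the 9 libraries of the other groups was left out.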

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

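Chosen only after the result was seen were the tests of a shortage of mitochondrial transcripts alone, of GC bias as the whole cause and of the GC trend in other libraries, of prior cell cycle arrest and of whether replicate 3 alone carries the knockdown calls, the count of splits by the pairs they part, and the alternatives with the GC offset.

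The interaction test found that the effect of irradiation differed between shTRIM22 and shControl cells for 276 genes. Camera with the preset correlation called 11 lists, of which only p53 targets, with a median of -0.76, stayed called with an estimated correlation. The calls of the others rest on the preset correlation. Their medians were -0.37 for mitosis and G2/M, with 0 of 30 genes called singly (adjusted p = 0.517 with an estimated correlation), -0.38 for DNA replication (0.234), -0.15 for DNA repair (0.371) and -0.37 for MHC class I presentation (0.183). They were -0.19 for the unfolded protein response and ATF4 (adjusted p = 0.138 with an estimated correlation), -0.24 for sterol genes (0.142) and -0.14 for ribosomal proteins (0.378). Above 0 were the medians of interferon-stimulated genes (0.25, adjusted p = 0.0546 with an estimated correlation), NRF2 targets (0.16, 0.207) and mitochondrially encoded genes (0.94, 0.489). Without shTRIM22 sham replicate 3 the medians of 3 lists moved by more than 1.5 times, to 0.45 for mitochondrially encoded genes, -0.21 for MHC class I presentation and -0.15 for sterol genes, and all 3 stayed called with the preset correlation. Named genes whose log2 effect of irradiation was lower in shTRIM22 cells by this test were ALPP (-3.13), SAA2 (-2.65), SAA1 (-2.20), PXDN (-1.66), FLG (-1.66), MDM2 (-1.22), ZMAT3 (-1.18), FANCD2 (-1.18), SESN1 (-1.12), AEN (-1.08), CDKN1A (-1.05), TP53INP1 (-0.99), CDT1 (-0.97), SPATA18 (-0.97), RPS19 (-0.90), KLF2 (-0.77), TYMS (-0.72), BBC3 (-0.71), VLDLR (-0.67), TIMP2 (-0.64), MCM4 (-0.62), PCNA (-0.57), KRT8 (-0.50), BAX (-0.49), JUN (-0.44) and B2M (-0.39). A lower log2 effect was a smaller rise for genes such as MDM2 and CDKN1A. For others it was a larger fall, as for KLF2 (-0.89 in shControl and -1.67 in shTRIM22 cells). Named genes whose log2 effect was higher were ABCC3 (0.33), ABCC2 (0.44), FOS (0.55), FOSB (0.88), MAP2 (1.04), ADGRE1 (1.14), MAP1A (1.23), PLEKHG6 (1.68) and APOH (2.66).

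The p53 targets rose less with irradiation in shTRIM22 than in shControl cells, with a median difference of -0.76. Without shTRIM22 sham replicate 3 the median was -0.82 and with an offset per library for GC content -0.73, and the list stayed called in both, which argues against that library or GC content as the whole cause. Prior arrest of unirradiated shTRIM22 cells was tested by whether mitotic and replication genes were lower there. Of the replication genes, 23 of 30 were higher and 1 lower, with a median of 0.53 (camera adjusted p = 0.29 with an estimated correlation). This argues against an arrest that lowers replication genes. An arrest that does not lower them cannot be excluded by this test. The mitotic list, with 6 higher and 2 lower of 30, was not called and decides nothing. By construction the interaction is also the knockdown effect after irradiation minus that without it. The p53 list had a median knockdown effect of 0.84 without irradiation, 24 of 30 being higher. After irradiation the median was 0.08 and the list was not called (camera adjusted p = 0.594). The smaller rise thus goes with a raised level before irradiation and a similar level after it. Whether loss of TRIM22 or another difference between the populations lies behind the raised level was not tested.

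In shTRIM22 sham replicate 3, the mitochondrial share was 2.67% and nuclear genes also deviated from the other libraries of the group. Its deviation from them followed GC content (Spearman rho = 0.372 across nuclear genes, which are not independent), against 0.0442 for the difference between replicates 1 and 2 and at most 0.270 in size in the 9 libraries of other groups, so GC bias may play a part. GC bias as the whole cause is argued against, since removing the trend took the SD from 0.369 to 0.341, above the 0.122 to 0.252 of all other libraries. A wrong group label is argued against by a correlation of 0.982 with its own group and 0.971 with the nearest other, a difference of 0.0111, and a shortage of mitochondrial transcripts alone by nuclear genes, which differed by 2.49 times the SD between the other libraries of the group. What else set this library apart stays open, and no biological explanation was tested.

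Many genes differed between shTRIM22 and shControl cells, 8116 without irradiation. Of these, 90.9% remained called without shTRIM22 sham replicate 3, so that library alone is not the cause. Copy-number differences of large segments are argued against, as the largest median of a 20 Mb window shared by both knockdown comparisons was 0.16 in 153 windows of at least 20 genes. Differences of smaller segments, and differences between the stable populations other than TRIM22, stay open.

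Other splits of the libraries were fitted as well. For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 3107 against at most 0 for irradiation in shControl cells, 4702 against 0 in shTRIM22 cells, 8116 against 0 for knockdown without irradiation and 6092 against 1 after irradiation. For knockdown without irradiation, where the replicate numbers may pair the libraries, 4 of the 10 splits part all 3 possible pairs as the real one does, and the 6 others part 1 pair. For the interaction, 6 of 100 drawn splits of the irradiation labels within each population, of 200 possible, gave at least 276 genes, the real split included. The others gave 491, 503, 596, 601 and 5831 genes. Each exchanged the labels of all 6 libraries of shTRIM22 with 0 or 2 of shControl, or of 4 libraries of shControl with 0 of shTRIM22. Such splits add up parts of the real irradiation effects of both populations, most of all the split with 5831 genes, which points to a structure of the samples. They are no chance level, so this count of splits does not decide whether chance can be excluded.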

How the results depend on the processing

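Chosen only after the data were seen were limma-voom with sample weights, the GC offset, the replicate block in a fit of the sham groups alone or with the GC offset, and leaving out shTRIM22 sham replicate 3 from comparisons without its group.

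No result reversed. Of 3817 values of named genes 3707 stayed called in their direction and 110 lost the call, and of 765 list values 701 stayed and 64 lost it, 37 of them with an estimated correlation. All alternatives were kept by 218 of 233 gene results and 18 of 55 list results. For irradiation in shControl cells the count of 3107 became 5224 with only the 2 compared groups, 5260 without shTRIM22 sham replicate 3 and 5813 with sample weights. For irradiation in shTRIM22 cells the 4702 became 2912 with only the 2 compared groups and 7741 with sample weights. For the interaction the 276 became 578 with the DESeq2 Wald test, 754 without a filter, 2594 with sample weights and 422 with the GC offset. Replicate 3 had a sample weight of 0.108, and it is in the libraries compared in shTRIM22 cells and not in those of shControl cells. Other causes were not tested.

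Leaving out each library of the groups compared in turn gave 2135 to 2355 genes for irradiation in shControl and 3356 to 5389 in shTRIM22 cells, 7047 to 8692 for knockdown without and 5009 to 5077 after irradiation, and 111 to 1185 for the interaction, where fewer libraries also give fewer degrees of freedom. TRIM22 ran from -3.01 to -2.68 without and from -3.31 to -2.91 after irradiation.

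Besides the sham groups, the 5 other pairs of groups did not pass the check of replicate numbers. Their same-number correlations of deviations ran from -0.0970 to 0.171, and the libraries that correlated best with their own number were 0 to 4 of 6. With the replicate block the counts were 3114, 4735, 8110, 6114 and 229, and TRIM22 changed by -2.86 and -3.15. For knockdown without irradiation the block gave 6643 genes in a fit of the 2 groups alone and 8323 with the GC offset. Of the 8116 genes, 7932 stayed called with the block, 6556 with the block in the 2 groups alone and 7774 with the block and GC offset. Among named genes and lists of that comparison it changed no other call than the BCL2 family and caspase list, which was lost with the GC offset without and with the block. Total counts of 14468386 to 17872154 limited genes of few counts, such as TRIM22 with 5 or 6 counts in shTRIM22 sham libraries.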

Other observations

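Chosen only after the result was seen were the values of CA9 and MARCOL, the choice of liver-type and zinc-finger genes, and the test of the latter.

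Genes of liver-type plasma proteins were lower in shTRIM22 cells. After 10 such genes were seen among large falls, a list of 50 others was written, of which 31 were tested. Without irradiation 24 of them were lower and 0 higher, with a median log2 fold change of -0.77, and after irradiation 20 were lower and 1 higher, with a median of -0.73. Examples, as log2 fold change without and after irradiation, were the fibrinogen gene FGB (-1.52 and -1.41), the inhibitor heavy chain gene ITIH2 (-1.64 and -1.28) and the nuclear receptor NR1H4 (-2.13 and -1.83). The transcription factor gene HNF4A, at -0.27 and -0.05, did not pass the test. The larger camera p of both comparisons was 2.93e-10, and the p-values with an estimated correlation were 0.00108 and 0.000592, which is consistent with a wider loss of such genes in these cells as a hypothesis. With irradiation these genes moved the other way, with 13 higher and 0 lower in shControl cells and 14 higher and 1 lower in shTRIM22 cells.

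Zinc-finger genes of chromosome 19 were looked at because many seemed higher in unirradiated shTRIM22 cells, where 44 of 153 tested were called higher and 13 lower (odds ratio 2.96 against other called genes, Fisher's exact p = 0.000266). After irradiation 21 were higher and 15 lower (two-sided Fisher's exact p = 0.319), so a rise of the class in both comparisons was not borne out. With irradiation 0 rose and 7 fell in shControl cells, where 58.7% of other called genes rose (two-sided Fisher's exact p = 0.00207). In shTRIM22 cells 0 rose and 24 fell, where 49.3% of other called genes rose (two-sided Fisher's exact p = 1.24e-07). The class was picked for high values in the unirradiated shTRIM22 libraries, which are the baseline of irradiation in shTRIM22 cells. A fall there was thus favoured in advance, and its p-value gives no independent support. Genes are not independent in these tests.

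By a rule of at most 1 count in every library of one population and at least 1 CPM in every library of the other, 1 gene, CA9, was off and 1 gene, MARCOL, was on in shTRIM22 cells.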
